A study of Caenorhabditis elegans with 3 samples.

How the data were processed

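ChIP-seq against tagged MML-1 was measured in 3 biological replicates of whole L3 larvae of mixed sex, per the labels. Per the labels, replicates 1 and 2 have a size range of 150 to 350 and a stock centre as source, and replicate 3 has sonication and the submitting laboratory as source. The labels describe the tag both as eGFP and as a C-terminal GFP-FLAG fusion. The authors deposited lists of regions for each replicate and a pooled list called on the 3 replicates together, in the ce10 and ce11 builds. They label the pooled list as peaks and background, the input to thresholding by the irreproducible discovery rate. A list of reproducible peaks after that thresholding was deposited in both builds. Pooled regions outside the reproducible list are therefore not a set of binding sites. Regions were called against a control library, which was not analysed here. The aligner, the peak caller and the rate threshold are not given in the sources used here.

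Each region has a signal value deposited by the authors, which describes the ChIP against the control on a scale of its own list. Each region also has a −log10 q-value deposited by the authors, which takes its highest value in all 195 reproducible peaks and was not used to rank. Region widths are nearly uniform within a list: 29961 of 30000 pooled regions are 284 bp wide, and most regions of replicates 1, 2 and 3 are 264, 260 and 360 bp wide. Summits, given per region by the authors, were therefore used to place regions. Read totals were not in the lists, so depth is unknown and intervals cover only the number of regions.

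The ce11 lists were the main lists and were read with the WBcel235 assembly and Ensembl release 115 annotation, whose chromosome lengths hold all regions. Coordinates are 1-based. The background was the 29797 pooled regions that overlap no reproducible peak. Promoter windows ran from 1000 bp upstream to 200 bp downstream of every protein-coding transcript start. Sequences were read within 100 bp of the summit. Non-coding RNA genes were annotated tRNA, snRNA, snoRNA, rRNA, miRNA and spliced leader RNA genes, and a peak within 200 bp of one was counted. Summits of different replicates within 200 bp were matched.

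Shares were compared by two-sided Fisher's exact tests with exact Clopper-Pearson intervals of 95%. Benjamini-Hochberg adjustment was applied over 10 CANNTG hexamers, 2080 hexamers, 6 chromosomes and 26 gene lists, each as its own family. A gene list was compared with all 7956 protein-coding genes that had a pooled summit in the window. Replicate matches were compared with 1000 draws of 1000 random regions, and the transgene loci with 10000 random windows on the same chromosome. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

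The tests of replicate matches, of promoter, hexamer, chromosome and non-coding RNA shares, of gene lists and of transgene loci were fixed before the data were examined, as were the gene lists and the rule for named genes. The rule names the 20 reproducible peaks of highest signal with their promoter or nearest gene, up to 4 members of each list with a peak in the window, the 5 highest peaks with CACGTG, and mml-1, mxl-2 and unc-119 whatever their values. All other tests were added later, such as those of annotation class, of CACGTG in and outside promoter windows, of clusters, of ranks in replicate 3 and of the bases and gaps next to CACGTG.

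The hexamer and gene list steps were tested on simulated data. A hexamer planted in pooled sequences was placed first among 2080 at 2 of 3 planted shares, and it was not placed first at the lowest. Over 10 random sets of pooled regions, 0 hexamer calls and 0 gene list calls were made. A planted gene list was called. Alternatives varied the build, the peak set, the promoter and summit windows, the background, the matching of replicates and the replicates used. One gene symbol of the lists, elt-5, was not matched in the annotation.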

Results

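Binding of MML-1 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L3 larvae of Caenorhabditis elegans. MML-1 is a basic helix-loop-helix leucine zipper protein of the Mondo family, which pairs with the Max-like protein MXL-2. The strain carries an integrated transgene that expresses MML-1 with a GFP-FLAG tag, together with a rescue of the unc-119 mutation. The labels give 3 biological replicates and no second condition, so the replicates were compared with one another and the reproducible peaks with the other regions of the pooled list. The pooled list, of peaks and background, held 30000 regions. The lists of replicates 1 and 2 held 30000 each and that of replicate 3 held 27021. The lists carry no read totals, so the depth of each library is unknown. Each region's signal is the authors' own value and was used only to rank regions within a list. The units of the tests are regions, not samples, so their p-values and intervals do not cover the spread between animals.

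The authors' reproducible list in the ce11 build held 195 peaks, which were the 195 regions of highest signal in the pooled list. The highest lay in an intron of Y62E10A.13 (WBGene00013379) on chromosome IV, 13395300 to 13395581, with a signal of 841.7. The next lay 132 bp upstream of mdl-1 (WBGene00003163), which encodes a Mad-like partner of the Max family, on chromosome X, 6742090 to 6742411, with a signal of 620.8. The peak at rank 3 lay in tre-2 (WBGene00006608), a trehalase gene, on chromosome IV, 6878993 to 6879239, within an intron and 238 bp upstream of an internal transcript start. Ranks 4 and 5 lay in an intron of Y43F8B.2 on chromosome V, 19529247 to 19529504, and 667 bp upstream of ZK829.7 on chromosome IV, 11962081 to 11962329.

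These 5 were also the 5 highest peaks with the hexamer CACGTG, the E-box bound by this protein family, within 100 bp of the summit. The site and its flanks read CGTTGTTCACGTGTACTTTT at Y62E10A.13 and CGAGGCGCACGTGCATACAC at mdl-1. They read GGCAATTCACGTGAAGCAGA at tre-2, CGCAATGCACGTGAATCGCC at Y43F8B.2 and TGCTTTTCACGTGCACACAA at ZK829.7. Of the 20 highest peaks, 16 held CACGTG, 10 lay in a promoter window and 9 lay on chromosome X. In all 3 replicates 18 of the 20 ranked among the first 100 regions.

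The remaining peaks of the first 20 that lay in promoter windows were at T07E3.4, F56H9.2, F22F7.7, the mannosidase gene mans-3, R07E3.4, the importin gene imb-3 and H18N23.2. Those outside a promoter window had F26A3.4, nhr-35, CC8.2, R03E9.2, E01G4.3 and acl-12 as the nearest genes, and mdl-1 for a pair of them. The peak near nhr-35, a nuclear hormone receptor gene, lay 2097 bp upstream on chromosome X, 4530487 to 4530696. It ranked 6 in replicate 1, 4 in replicate 2 and 783 in replicate 3. The 4 peaks of the first 20 without CACGTG were this one and those at F26A3.4, T07E3.4 and F22F7.7.

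The mdl-1 locus held 10 reproducible peaks within 13.9 kb of chromosome X, 6736571 to 6750441, and 8 of them had CACGTG. They lay upstream of mdl-1, within its intron, downstream of it and in an intron of the neighbouring gene abts-4. The peak in abts-4 at 6750162 to 6750441 ranked 7 in the pooled list, and the peak 1677 bp downstream of the mdl-1 start ranked 16.

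**Figure D1:**
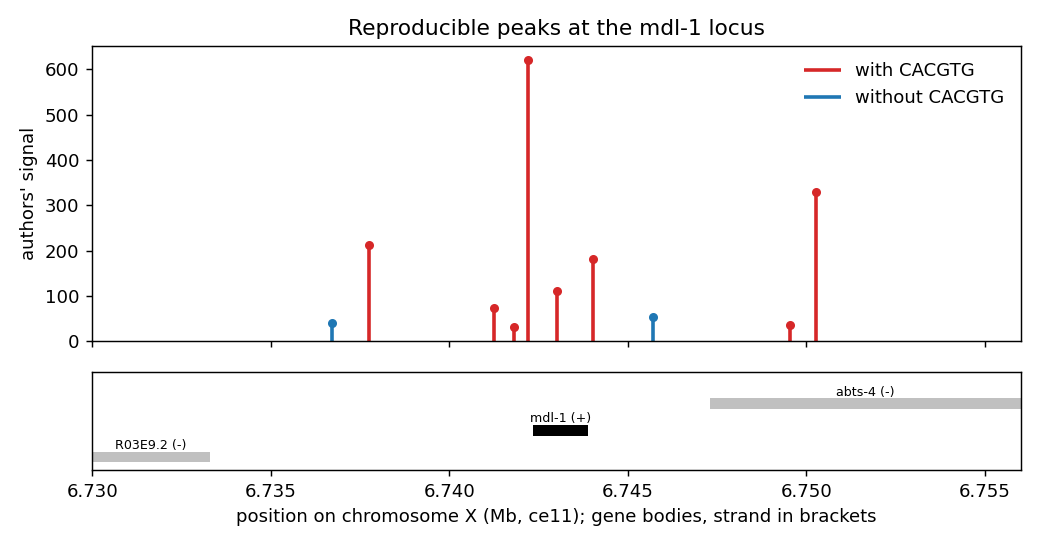
Reproducible peaks at the mdl-1 locus, with the position on chromosome X (ce11, Mb) on the x axis and the authors' signal on the y axis. Each line is a peak, red with CACGTG and blue without, above the annotated gene bodies. The highest line is the peak 132 bp upstream of mdl-1.

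Replicates were compared to ask how far separate libraries gave the same places. Of the 1000 highest regions of replicate 1, 179 had a top region of replicate 2 with a summit within 200 bp and 215 had one of replicate 3. For replicates 2 and 3 the number was 144. Replicate 1 had 118 regions matched in both other replicates, or 11.8%, where random draws gave a mean of 0.0056% (one-sided permutation p = 0.000999, the smallest that 1000 draws can give). Among the 195 reproducible peaks, 112 lay near a top 1000 region of each replicate, 73 of 2 replicates and 10 of 1 replicate. By replicate, 178, 148 and 166 of them were near a top 1000 region of replicates 1, 2 and 3.

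**Figure D2:**
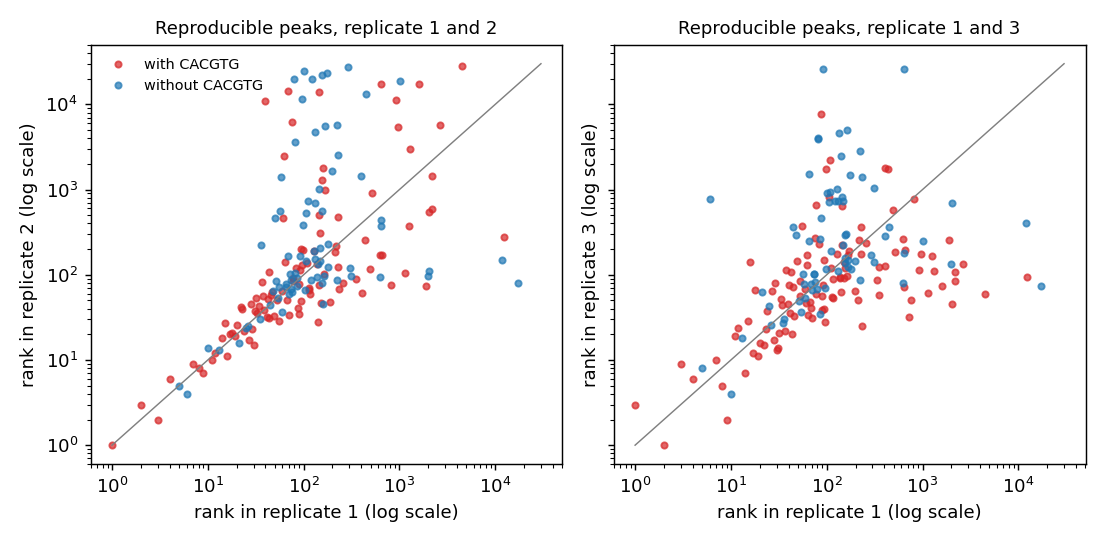
Ranks of the reproducible peaks in replicate 1 (x axis) against replicate 2 (left) and replicate 3 (right), on log axes. Each point is a peak, red with CACGTG and blue without, the grey line marks equal ranks and peaks with no region in a replicate (1, 14 and 11 for replicates 1, 2 and 3) are left out. The highest peaks, such as those at Y62E10A.13 and mdl-1, lie close to the line in both panels.

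The sequence under the summits was compared to ask which motif marked the peaks. CACGTG lay within 100 bp of the summit in 116 of 195 reproducible peaks, or 59.5% (95% exact interval 52.2 to 66.4), and in 4.31% (4.08 to 4.54) of 29797 other pooled regions. The odds ratio was 32.6 (two-sided Fisher's exact test, p = 9.68e-103, adjusted p = 9.68e-102 over 10 CANNTG hexamers). The related hexamer CACATG was present in 60 peaks, or 30.8%, against 7.81% of the other regions (Fisher's exact test, adjusted p = 7.04e-20). CAGCTG was more frequent in peaks, at 10.3% against 4.59%, and CAAATG less frequent, at 11.3% against 18.3% (Fisher's exact test, adjusted p = 0.00284 and 0.0290). Adjusted over all 2080 hexamers, CAAATG did not pass (Fisher's exact test, adjusted p = 0.0502). The other 6 CANNTG hexamers did not pass the threshold.

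The CACGTG site nearest to the summit lay at a median of 12 bp from it, and 86 of the 116 peaks had it within 25 bp. In all, 93 peaks held 1 site and 23 held 2 or more. CACGTG was found in 53.3% of the 92 peaks in promoter windows and in 65.0% of the 103 peaks elsewhere, a difference that did not pass the threshold (two-sided Fisher's exact test, p = 0.109).

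**Figure D3:**
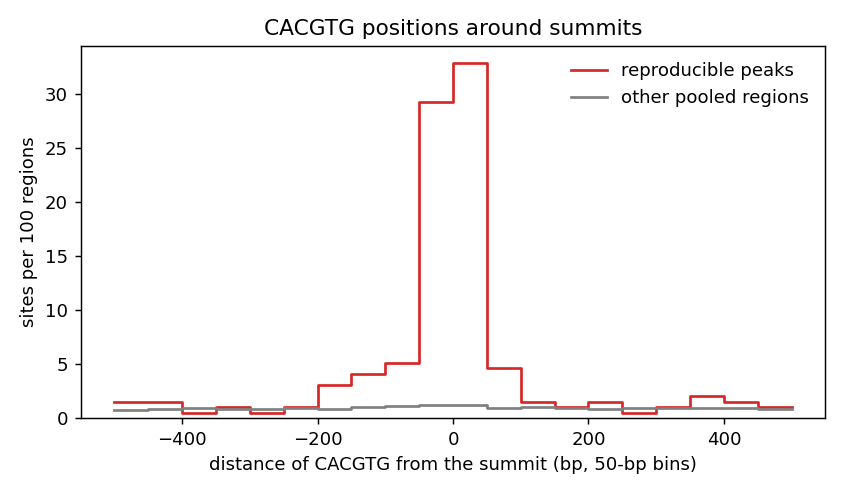
CACGTG sites per 100 regions in bins of 50 bp (y axis) by distance from the summit in bp (x axis). The red line shows reproducible peaks and the grey line other pooled regions. In the bins next to the summit the peaks have 29.2 and 32.8 sites per 100 regions, where the other regions have 1.27 and 1.25.

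A search over all 2080 hexamers, each merged with its reverse complement, placed CACGTG first. It found 289 hexamers more frequent in peaks and 191 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05). The overlapping hexamers ACGTGA and ACGTGC came next, in 48.2% and 31.3% of peaks. AGAGAC was in 37.9% of peaks and 9.14% of other regions (Fisher's exact test, adjusted p = 1.05e-24). Against 975 regions matched on GC content and promoter position 58 hexamers were more frequent, and against 975 random other regions 254 were, with CACGTG first in both.

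CACGTG was also more frequent among the top 1000 regions of each replicate. The share was 17.5% in replicate 1, 12.9% in replicate 2 and 21.8% in replicate 3, or 17.4% ± 4.45 (SD, n = 3), against 4.04% ± 0.266 (SD, n = 3) in the other regions of each list. Within each replicate the difference passed Fisher's exact test (p = 1.84e-58, 3.47e-30 and 1.10e-80). With 3 replicates, a two-sided exact paired test across them cannot go below p = 0.25. Among top regions of replicate 1, CACGTG was in 62.7% of the 118 shared with both others, 34.8% of the 158 shared with 1 other and 6.35% of the 724 shared with none.

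**Figure D4:**
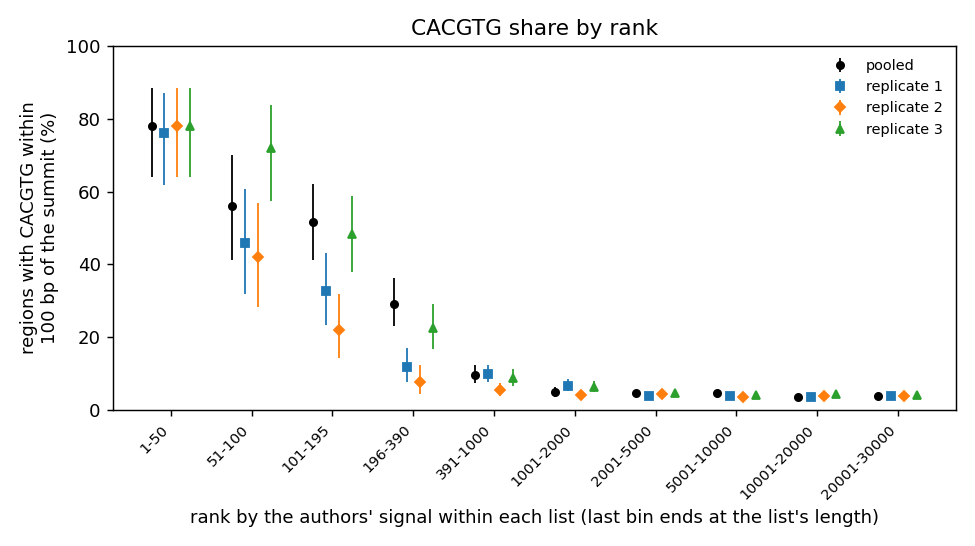
Share of regions with CACGTG within 100 bp of the summit (y axis, %) by rank bin (x axis) in the pooled list and each replicate. Points are shares and bars are 95% exact binomial intervals. In the first 50 regions the share is 78.0% in the pooled list and 76.0% to 78.0% in the replicates, and it falls to about 4% in the last bins.

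Peaks were next placed against genes. Of the 195 summits, 92 lay from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, or 47.2% (95% exact interval 40.0 to 54.4), against 29.2% (28.7 to 29.8) of other pooled regions. The odds ratio was 2.16 (two-sided Fisher's exact test, p = 1.42e-07). These windows belonged to 96 genes. By annotation, 125 summits were intergenic, 62 lay in introns, 4 in 5′ UTRs and 4 in coding exons.

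Genes of the Myc, Mondo and Max network were over-represented among the 96 genes. Of its 5 members, 4 had any pooled region in the window and 3 had a reproducible peak, where 0.0483 were expected (two-sided Fisher's exact test, adjusted p = 0.000176 over 26 lists). They were mdl-1, at rank 2, mxl-3 (WBGene00003511), at rank 157 and 310 bp upstream on chromosome X, 13350972 to 13351255, and mml-1 itself, at rank 175. The peak of mml-1 (WBGene00003378) in the window lay 947 bp upstream on chromosome III, 7375536 to 7375819, and a further peak at 7376444 to 7376727 lay 1855 bp upstream and held CACGTG. The promoter peaks of mxl-3 and mml-1 had no CACGTG and ranked 712 and 2825 in replicate 3. Outside the window, mxl-3 was also nearest to a peak with CACGTG at rank 32, 2852 bp upstream, and to one without at rank 169. The gene mxl-2 (WBGene00003510) had no reproducible peak, and the best pooled rank within 20 kb of it was 4468. The network was still called, with 2 members, when peaks within 20 kb of mml-1 and unc-119 were left out. It was no longer called, with 1 member, among the 98 peaks of highest signal or with 1 peak per 10 kb cluster (Fisher's exact test, adjusted p = 0.572 and 0.264).

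The list of pentose phosphate, trehalose and glycogen genes had a peak at 3 of 12 members with a region, where 0.145 were expected (Fisher's exact test, adjusted p = 0.00450). They were the trehalase genes tre-2, at rank 3, and tre-1 (WBGene00006607), at rank 189 and 29 bp upstream, and the trehalose phosphate synthase gene tps-2 (WBGene00006603), at rank 178 and 721 bp upstream. The peak at tre-1 also lay in the window of dad-1. The promoter peaks of tre-1 and tps-2 had no CACGTG and ranked 13234 and 27195 in replicate 2. Outside the window, tps-2 was also nearest to a peak with CACGTG at rank 142, 2348 bp upstream. Among the top 1000 regions shared by replicates 2 and 3, and among those shared by replicates 1 and 2, the list had 1 member and was not called. The call also ended with the top 1000 pooled regions, the 98 peaks of highest signal, 1 peak per 10 kb cluster and the window of 500 bp upstream to 100 bp downstream (Fisher's exact test, adjusted p = 0.126, 0.694, 0.142 and 0.0651).

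The autophagy list had peaks at 2 of 16 members and did not pass the adjusted threshold (Fisher's exact test, p = 0.0155, adjusted p = 0.134). They were lgg-2 (WBGene00002981), an LC3 homologue, at rank 38 on chromosome IV, 10935444 to 10935564, and atg-9 (WBGene00020706), at rank 106 on chromosome V, 349091 to 349374. The peak at lgg-2 ranked 36, 223 and 30 in replicates 1, 2 and 3. That at atg-9 ranked 749 and 50 in replicates 1 and 3 and had no region within 200 bp in replicate 2. The autophagy list did pass with the window of 2000 bp upstream to 500 bp downstream and with the top 1000 pooled regions. The heat shock list had 2 of 27 members, hsp-110 (WBGene00016250) at rank 83 and hsp-3 (WBGene00002007) at rank 163 (Fisher's exact test, p = 0.0416, adjusted p = 0.270). The peak at hsp-110 also lay in the window of rpn-3, whose start was nearer. It ranked 50 and 465 in replicates 1 and 2 and had no region within 200 bp in replicate 3. The peak at hsp-3 ranked 11904, 149 and 410 in replicates 1, 2 and 3. Of 103 nuclear hormone receptor genes with a region, 1 had a peak in the window, nhr-35 (WBGene00003628), at rank 77 and 384 bp upstream (Fisher's exact test, adjusted p = 1).

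The other 21 lists had no member with a reproducible peak in the window. They covered glycolysis, lysosome, fatty acid synthesis and oxidation, ribosomal proteins, TOR and insulin signalling, arrestin domain proteins, redox defence, collagens, moulting, Wnt and semaphorin genes, homeobox genes, histones, mitochondrial respiration and ribosomes. They also covered markers of intestine, muscle, pharynx, neurons, hypodermis and germline. At most 0.821 members were expected in any of them, so a lack of binding cannot be read from these counts.

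Of the 195 peaks, 10 lay within 200 bp of a short non-coding RNA gene, or 5.13% (95% exact interval 2.49 to 9.23), against 1.28% of other regions (odds ratio 4.18, two-sided Fisher's exact test, p = 0.000254). By class, 5 peaks were near tRNA genes, 4 near snoRNA genes and 1 near an snRNA gene, R07E5.16 on chromosome III. The highest of these peaks ranked 81 and none of the 10 had CACGTG. The share was 8.38% in regions shared by replicates 1 and 2, and 2.08% and 2.79%, no longer past the threshold, in regions shared by replicate 3 with replicates 2 and 1.

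Chromosome X held 54 reproducible peaks, or 27.7% (95% exact interval 21.5 to 34.5), against 21.1% of other regions. The difference did not pass after adjustment over 6 chromosomes (Fisher's exact test, p = 0.0279, adjusted p = 0.167). No other chromosome passed, with adjusted p from 0.495 to 0.786 by the same exact test. The share on X passed with the top 1000 pooled regions, at 26.0%. It also passed when replicate 1 or replicate 3 was left out, at 32.6% and 31.8%. There the reproducible peaks were replaced by top 1000 regions shared by the other replicates, so the peak set and the replicates changed together. With 1 peak per 10 kb cluster the share on X was 23.9% (Fisher's exact test, adjusted p = 0.918).

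The loci carried by the transgene were examined apart. Within 20 kb of mml-1, on chromosome III from 7350130 to 7394731, the pooled list had 39 regions, where random windows of the same length on the chromosome had a mean of 13.2 (one-sided permutation p = 0.00060). The number was 30, 32 and 23 in replicates 1, 2 and 3, each above the random mean (permutation p = 0.0040, 0.00080 and 0.0039). Within 20 kb of unc-119 (WBGene00006843), from 10882641 to 10928935, there were 17 pooled regions against a mean of 13.7 and no reproducible peak (permutation p = 0.287). The best rank at mml-1 was 151, and at unc-119 it was 3655 (one-sided permutation p = 0.0438 and 0.705).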

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

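The alternatives that keep 1 peak per 10 kb cluster or draw a random background of 975 regions were chosen after seeing the data. The E-box share, the E-box share per replicate, the promoter share, the replicate agreement and the excess of regions at mml-1 kept their direction and their side of the threshold under every alternative run for them. The E-box share ranged from 23.2% with the top 1000 pooled regions to 67.3% with the 98 peaks of highest signal, and the promoter share from 30.8% to 60.0%. The ce10 list held 189 reproducible peaks and no peaks overlapped one another.

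A stricter list of the 98 peaks of highest signal gave 181 enriched hexamers, 0 called gene lists and a non-coding RNA share of 3.06%, no longer past the threshold. With the top 1000 pooled regions 525 hexamers were enriched and the chromosome X share of 26.0% passed, while the list of pentose phosphate, trehalose and glycogen genes lost its call and the autophagy list gained one. Against 975 matched regions 58 hexamers were enriched, and against one random draw of as many regions 254, so the smaller number of regions alone does not account for the lower count. Gene list calls fell to 0 with 1 peak per cluster, which by construction drops the promoter peaks of mxl-3, mml-1 and tps-2, and to 1 with the window of 500 bp upstream to 100 bp downstream. With summits required inside the non-coding gene body, the share was 0, below that of other regions, but only 0.438 peaks would be expected there, so no direction can be read from it.

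To leave out replicate 1, 2 or 3, the reproducible peaks were replaced by the 144, 215 or 179 top 1000 regions shared by the other replicates. This gave 1 to 2 called gene lists, a non-coding RNA share of 2.08% to 8.38% and a chromosome X share of 25.1% to 32.6%. The peak set and the replicates changed together, so a change cannot be put down to a replicate alone. In the lists of the other replicates, the mean number of regions within 20 kb of unc-119 was 11.5 to 14.5, on either side of the random mean. The causes were not tested. Depth is unknown, so a peak that is low in 1 replicate cannot be set against its reads.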

Other observations

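The tests of clusters, of ranks in replicate 3 other than the split by CACATG, of CACATG against matched regions, of crowded sites and of the ranks below the reproducible set were chosen after the results were seen. The comparison of unc-119 with random windows was planned, but what it would show if copies raised the signal was set down after the reproducible peaks had been seen, and extended to each replicate after those ranks had been seen. The genes of the next paragraph, outside the rule for named genes, were also chosen after their values were seen.

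Several peaks with CACGTG lay outside the promoter window at genes of the fixed lists. In the FOXO gene daf-16 a peak at rank 22 lay in an intron on chromosome I, 10751698 to 10751871, 825 bp downstream of a transcript start. In aak-2, which encodes a catalytic subunit of AMP-activated kinase, a peak at rank 68 lay in an intron 918 bp downstream of a start. The autophagy genes epg-9 and atg-2 held intronic peaks at ranks 28 and 100, at 974 and 804 bp downstream of a start. The pyruvate kinase gene pyk-1 had a peak 1342 bp upstream at rank 54, and the ATP-citrate lyase gene acly-1 had one in a coding exon at rank 65. The peak at acly-1 had no region within 200 bp in replicate 2. Farther out, at 1591 to 6635 bp from a start, peaks with CACGTG had the nuclear hormone receptor genes nhr-19, nhr-105, nhr-119, nhr-11 and nhr-46 as nearest genes. Coding exons held 2.05% of the reproducible peaks and 29.3% of a sample of 2000 other pooled regions (Fisher's exact test, adjusted p = 1.36e-21). Intergenic summits made up 64.1% and 34.9% (Fisher's exact test, adjusted p = 8.31e-15).

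Reproducible peaks lay in clusters, as at mdl-1, at mxl-3 with 5 peaks in 9.27 kb, and at T07E3.4, CC8.2 and H18N23.2 with 4 each. In all, 85 of 195 peaks had another within 10 kb, where random sets of pooled regions had a mean of 8.47 and a highest value of 22 (permutation p = 0.000999), which argues against chance placement. The lower ranked peaks of the clusters had CACGTG in 31 of 53, or 58.5% (95% exact interval 44.1 to 71.9), and lay a median of 1464 bp from the nearest peak. For the lower ranked peaks as a set, this argues against calls split from a single enriched area. Such calls would carry the hexamer about as often as other regions. Split calls stay open for the lower ranked peaks without CACGTG. No biological explanation was tested.

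The peaks at mml-1 may come from extra copies of the transgene. The 39 pooled regions within 20 kb, against a mean of 13.2 (permutation p = 0.00060), are what copied DNA would give if the control lacks the copies. The control was not analysed, and the random windows were matched only on length and chromosome. The count therefore cannot tell extra copies from other causes. At unc-119, which the transgene also carries, the best pooled rank was 3655, where random windows had a median of 2045 (permutation p = 0.705). In replicates 1, 2 and 3 it was 869, 6059 and 5259 against medians of 1848, 1875 and 1526, so extra copies of unc-119 stay open. Binding of MML-1 upstream of its own gene stays open, since the peak at rank 151 holds CACGTG and copied promoters would be bound too.

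Peaks without CACGTG ranked lower in replicate 3. The median ranks of peaks without and with CACGTG were 249 and 75.5 in replicate 3, 110 and 93.5 in replicate 1, and 144 and 87.0 in replicate 2. Peaks with no region within 200 bp (1, 14 and 11 in replicates 1, 2 and 3) were counted as ranked below those listed. The difference between peaks without and with CACGTG, as log2 rank in replicate 3 less the mean of the others, was 1.57 (permutation p = 0.00060). Peaks with CACGTG had a mean of -0.678 in this measure, so part of the difference lies in these peaks. How far it rests on peaks with no region was not tested. The difference stayed past the threshold within 3 classes of pooled rank (permutation p = 0.0010) and with regions matched within 500 bp (permutation p = 0.0010). It also did so within promoter classes (permutation p = 0.0013) and without the peaks near non-coding RNA genes, where it fell to 1.08 (permutation p = 0.0204). Replicates 1 and 2 differed by -0.21 in the same measure, so the library of replicate 3, the only one with its source and fragmentation, cannot be told apart from a difference between animals.

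A hypothesis was that CACATG stands in for CACGTG. The 79 peaks without CACGTG had 137 enriched hexamers, or 18 against regions matched on GC content and promoter position, and CACATG had the lowest p, in 34 peaks or 43.0% against 7.81% of other regions. The matched regions had it in 4.30% (Fisher's exact test, adjusted p = 1.33e-14), so these properties do not account for it. Among all 195 peaks CACATG was in 60, so it also occurred beside CACGTG and not only in its place. AGAGAC and AAGAGA, in 34 and 39 of the peaks, also passed against matched regions (Fisher's exact test, adjusted p = 1.27e-05 and 7.66e-05). If CACATG stands in for CACGTG, peaks with it alone might keep their rank in replicate 3. Peaks with neither hexamer ranked lower there by 1.41 in log2 rank than peaks with CACATG alone, which did not pass the threshold (permutation p = 0.0684).

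A hypothesis of paired sites was tested on adjacent CACGTG sites up to 50 bases apart. Of 18 pairs in reproducible peaks, 5 had a gap of 5 bases, where equal gaps would give 0.353 (exact binomial p = 2.01e-05). In other pooled regions 3 of 51 pairs had this gap. Sites crowd at the summit, which makes short gaps frequent and equal gaps a poor reference. Gaps formed between site positions of different peaks gave 0.625 pairs at 5 bases (exact binomial p = 0.000295), so crowding alone does not account for the 5 if pairs are independent. The peak at rank 18 held 3 sites and can give more than 1 pair. The 5 bases before its listed site were the same as the 5 bases after it. The bases read beyond them matched the end and the start of further sites, as a local repeat with this gap would give. Pairs from such a repeat are not independent, so both binomial p-values may be too low. How many of the 5 pairs came from this peak was not recorded, and repeats at other peaks were not tested. Gaps of 3 to 7 bases made up 11 of the 18 pairs, where 3.01 were expected that way, with 1, 1, 2 and 2 pairs at 3, 4, 6 and 7 bases. A preference for 5 bases was not separated from one for short gaps, and the result rests on 5 pairs.

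Preferred bases next to CACGTG were also tested, and all 4 differed. T preceded CACGTG, read on either strand, at 47.5% of 280 flanks in reproducible peaks and 26.8% of 2678 in other regions (Fisher's exact test, adjusted p = 1.34e-11). G was also more frequent, at 23.6% and 15.5%, and C and A were less frequent, at 15.7% and 34.2% and at 13.2% and 23.5% (Fisher's exact test, adjusted p = 0.000841, 9.08e-11 and 6.07e-05). Both flanks of a site were counted, so flanks are not independent. The other regions were not matched on GC content or position here. Coding exons held 29.3% of a sample of them and 2.05% of the peaks. A preference for a base was therefore not separated from a difference in sequence make-up.

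CACGTG continued below the reproducible set. In pooled ranks 196 to 390 it was in 57 regions, or 29.2%, against 4.14% of all lower ranks (Fisher's exact test, p = 1.29e-31). The reproducible list may thus leave out regions of the same kind.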
